A study of Mus musculus with 8 samples.

How the data were processed

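RNA from primary mesothelial cells of the mouse omentum was measured in 8 libraries, 4 from WT cells and 4 from BAP1 KO cells, and grouped by the genotype given in the labels. Per the labels' protocols, RNA was purified on columns with DNase digestion, 0.5 µg went into a TruSeq RNA v2 library, and the libraries were sequenced on a HiSeq4000 as single-end reads of 50 bp. This kit does not mark the strand. Per the submitters' processing notes, GSNAP and the build GRCm38 were used; the aligner's version, the gene annotation and whether counting used the strand are not given in the sources used here.

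The deposited counts are whole numbers of uniquely aligning reads per gene, per the file headers, with genes given as Entrez identifiers. Beside them stand the authors' normalized RPKM values, RPKM adjusted by a size factor, per the file headers. Over the 13774 genes with enough counts, the ratio of count to RPKM varied between libraries by a relative spread of at most 0.0034 after 1 factor per library, so the RPKM hold the same measurements, and only the counts were tested. Because only uniquely aligning reads were counted, genes with near-identical copies hold fewer reads than they produced. Each file lists 36528 identifiers. Of these, 31049 were given a symbol from the RefSeq table of GRCm38.p6 and 77 from GENCODE vM21. The other 5402 identifiers, with 1.15 to 1.29% of the counts of a library, were tested without a symbol.

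Total counts per library were 67.1 to 84.9 M, above the 30 M reads that the protocol states; the reason is not given in the sources used here. For genes with at least 200 counts in each library, the median squared difference between libraries of a genotype was 2.38 to 5.37 times that of counting noise, so counting error alone does not account for the spread. Nothing in the labels says whether the 4 libraries of a genotype came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels name no batch, pairing or covariate. No pair of libraries of a genotype agreed within counting noise, so each was counted as a replicate.

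Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test with robust dispersion, TMM factors and the filter filterByExpr by genotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are BAP1 KO minus WT, and each standard error is the fold change divided by the square root of its F value. CPM are counts per M of the TMM-adjusted library total. Gene lists, 40 in all, were fixed before the data were examined, and the 38 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation, and with fry. The principal components used log2 CPM with a prior count of 2. On counts simulated for the real genes, with 200 genes of the comparison changed, the test recovered 38.0% of the genes changed by 1.1-fold, 79.6% at 1.25-fold, 81.6% at 1.5-fold and 87.8% at 2-fold, over 16777 genes tested. It called 8 of 16580 unchanged genes. In the simulated list test, a list of 30 genes raised by 1.25-fold passed, and neither random list did. Both simulations changed few genes and drew each gene independently of the others. In the real data 61.1% of the genes were called and genes may vary together, so these rates need not hold there.

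The genes named were chosen by a rule set before the data were examined. They are Bap1; the 12 largest changes in each direction among genes that passed the test, whose 4 BAP1 KO values all lay on one side of the 4 WT values and whose mean reached 1 CPM in a genotype; up to 4 members of each list with the smallest adjusted p among those that passed; and a fixed set of 19 genes of apoptosis, the Polycomb complexes, mesothelial cells and other cell types. Symbols of predicted models and pseudogenes were skipped, which removed 1 gene from the lower group and 0 from the higher group. Some genes that this rule chose are not reported here; they stayed in all tests and list counts. Overlap with other genes was read from GENCODE vM21, and gene coordinates from RefSeq on GRCm38.p6. Where exons of 2 genes overlap, reads of either may have been counted for the other or for neither.

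The alternatives were RLE factors, upper quartile factors, library totals alone, no filter on low counts, CPM above 1 in at least 4 libraries, DESeq2 1.42.0, limma-voom, 1 surrogate variable from sva 3.50.0, a test against a 1.5-fold change, an estimated correlation for the lists, and each library left out in turn. Removal of each library's trend with GC content and gene length was added after seeing the data. It used GENCODE transcripts and the length implied by the deposited values, and 85.1% of the tested genes had both.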

Results

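Expression was measured by sequencing of polyadenylated RNA in primary mesothelial cells, the cells that line the body cavities, taken from the omentum of mice. There were 4 WT libraries and 4 libraries with knockout of BAP1, a nuclear deubiquitinase that removes ubiquitin from histone H2A and is a tumour suppressor in mesothelioma. The comparison asks how loss of BAP1 changes gene expression in these cells. Other cell types may contribute to the RNA. In WT the macrophage marker Lyz2 stood at 8388 CPM, and the mesothelial markers Upk3b and Msln at 462 and 6.95 CPM. Which cells a change arose in was not measured, so the changes below cannot be assigned to mesothelial cells alone. WT libraries held 67.1, 84.9, 71.9 and 77.0 M counts, and BAP1 KO libraries 69.5, 78.2, 82.1 and 73.0 M. Between 21654 and 22267 genes had at least 1 count per library. All values below are means over n = 4 libraries per genotype, and log2 fold changes are given with their standard error.

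The targeted gene was lower in every BAP1 KO library, but by a small amount. Bap1 (Entrez 104416; GRCm38 chromosome 14, 31251352 to 31259930) stood at 63.2 ± 0.73 CPM (SD, n = 4) in WT and 53.2 ± 0.91 CPM (SD, n = 4) in BAP1 KO, which is 84.2% of the WT level. The WT libraries lay between 62.6 and 64.2 CPM and the BAP1 KO libraries between 52.0 and 54.0 CPM, on 3741 to 5318 counts each. The log2 fold change was -0.25 ± 0.03 (edgeR adjusted p = 2.1e-09), and an exact permutation test of the 8 values gave a two-sided p of 0.029, the smallest that 4 against 4 can give. Counts per gene do not show which exons the reads came from, and the labels do not name the deleted exons, so reads from exons outside the deletion check nothing.

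**Figure D1:**
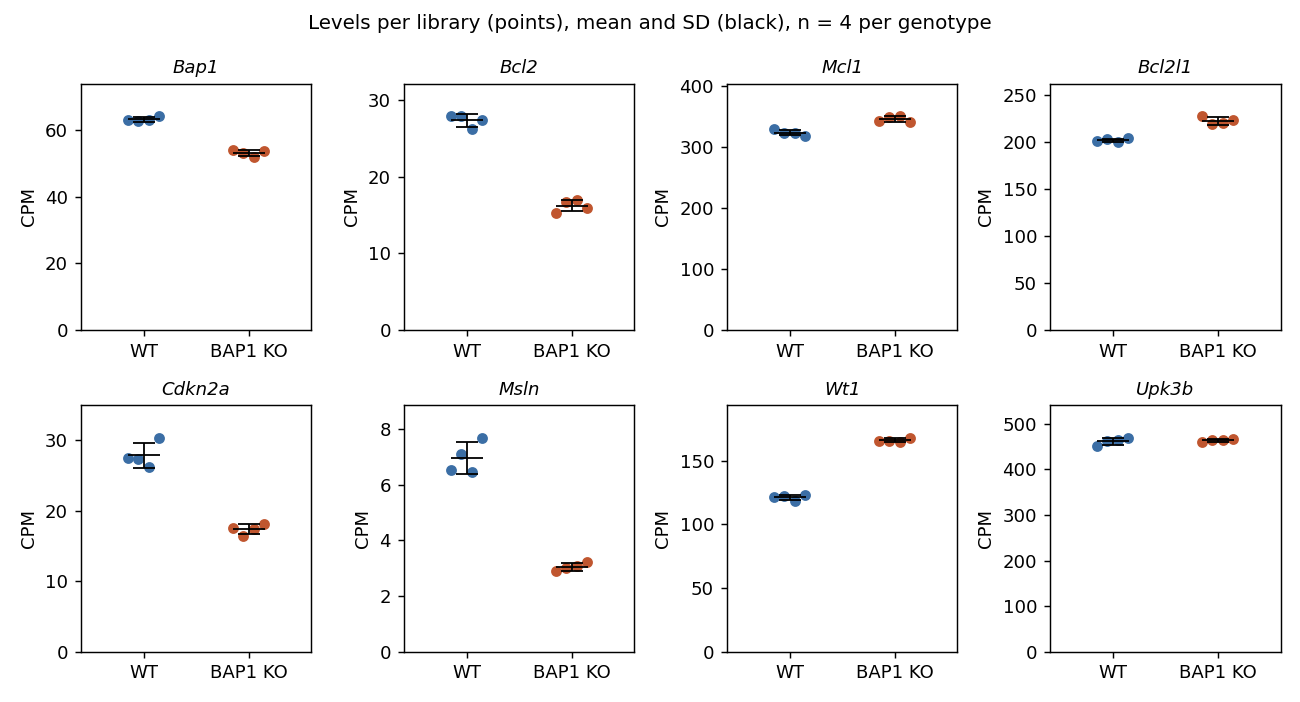
Level of 8 genes in CPM (vertical axes, from 0) in each WT and BAP1 KO library (points), with mean and SD in black, n = 4 per genotype. Bap1 lies between 52.0 and 54.0 CPM in BAP1 KO and between 62.6 and 64.2 CPM in WT, Bcl2, Cdkn2a and Msln are lower in BAP1 KO, Wt1 is higher, and Upk3b does not separate the genotypes.

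BAP1 KO and WT cells differed across much of the transcriptome, mostly by small amounts. Of 16929 genes tested, 4908 were higher and 5432 lower in BAP1 KO (edgeR, adjusted p below 0.05), 61.1% in all. Of those called, 75.8% changed by less than 1.5-fold. At 2-fold or more, 312 genes were higher and 772 lower. The genotypes did not overlap in 53.8% of the tested genes, where chance alone gives 2.86%. The first principal component held 71.8% of the variance and separated the genotypes. Libraries of a genotype were close to each other, with a biological coefficient of variation of 0.029, so that small differences pass the test. Against a 1.5-fold change, 370 genes were higher and 1014 lower.

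**Figure D2:**
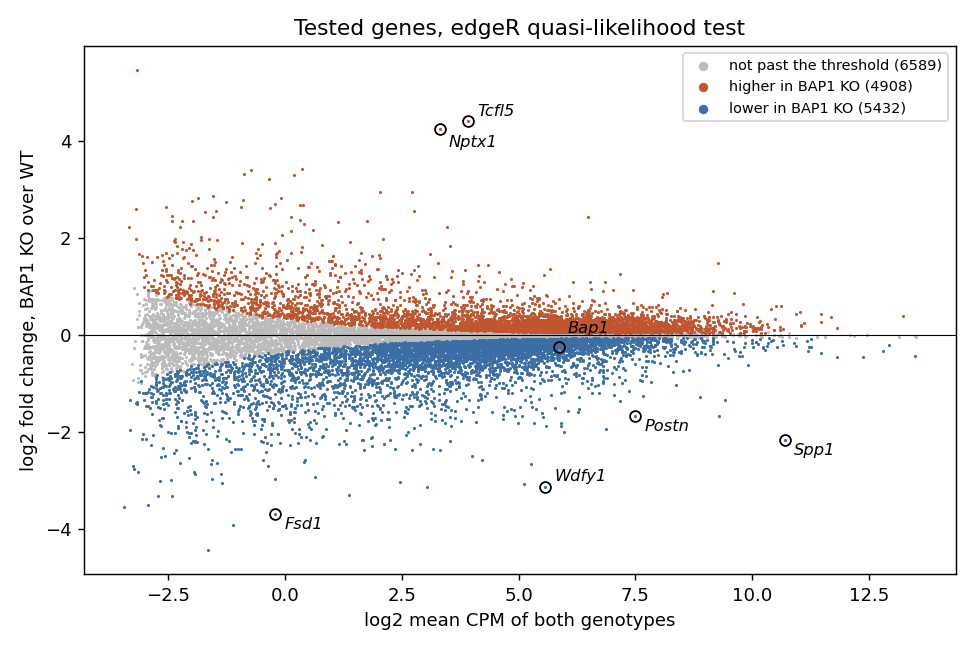
Log2 fold change of BAP1 KO over WT (vertical axis) against log2 mean CPM (horizontal axis) for the 16929 tested genes, coloured by the result of the edgeR test. Tcfl5 and Nptx1 are the largest rises and Fsd1 the largest fall that the rule chose; a few genes of lower abundance lie further out, and Bap1 lies at -0.25.

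The largest rises chosen by the rule were in genes that were near silent in WT cells. Tcfl5 (Entrez 277353; chromosome 2, 180621956 to 180642691), a basic helix-loop-helix transcription factor best known from the testis, rose from 1.36 ± 0.12 to 29.0 ± 0.26 CPM (SD), a log2 fold change of 4.42 ± 0.06 (adjusted p = 6e-32). Nptx1, a secreted neuronal pentraxin, rose from 0.99 ± 0.13 to 18.96 ± 1.1 CPM (4.25 ± 0.08). Nxph4, a neurexophilin, and Lrrc4, a synaptic adhesion protein, rose by 2.96 ± 0.08 and 2.96 ± 0.09, to 11.6 and 7.31 CPM. Crabp2, which carries retinoic acid, rose by 3.42 ± 0.16, and Cyp11a1, the enzyme that starts steroid hormone synthesis, by 2.70 ± 0.19. Tmem132e (3.22 ± 0.20), Slitrk5 (2.83 ± 0.20), Avil (2.69 ± 0.16), the actin-binding protein advillin, and Ryr3 (2.69 ± 0.16), a calcium release channel, completed the group at 1.43 to 2.26 CPM in BAP1 KO. Col9a3 (3.30 ± 0.21) is uncertain, because its exons overlap those of Tcfl5 on the opposite strand over 234 bp. Rpl39l (3.40 ± 0.32) is uncertain too, since it resembles Rpl39 and had 1 to 16 counts in WT. Exons of Avil, Ryr3 and Cyp11a1 also overlap those of a neighbour.

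The largest falls chosen by the rule included genes of macrophages, matrix and signalling. Wdfy1 (Entrez 69368; chromosome 1, 79702262 to 79776143), an endosomal adaptor protein, fell from 85.1 ± 1.3 to 9.76 ± 0.60 CPM (SD), a log2 fold change of -3.12 ± 0.04 (adjusted p = 3.6e-33); its exons overlap those of Mrpl44 on the opposite strand over 126 bp. Fsd1 had the lowest log2 fold change of the genes chosen, -3.69 ± 0.20, from 1.61 to 0.12 CPM. Gucy1b1, a subunit of soluble guanylate cyclase, fell from 14.8 to 1.70 CPM (-3.12 ± 0.07). The macrophage-associated genes Fcrls, Slamf9 and Mgl2 fell, with log2 fold changes of -3.06 ± 0.04, -2.57 ± 0.05 and -2.70 ± 0.19, Fcrls from 62.2 to 7.45 CPM. Thbs2, a matrix thrombospondin, fell from 66.2 ± 0.74 to 10.5 ± 0.71 CPM (-2.65 ± 0.04), and Frem1, a basement membrane protein, by 2.92 ± 0.16. Pgm5 (-3.02 ± 0.09), Tnfsf14 (-2.61 ± 0.17), a ligand of the tumour necrosis factor family, and Slc5a7 (-2.56 ± 0.21), a choline transporter, followed. Mir147 (-2.96 ± 0.20) lies within a longer transcript on the same strand, whose reads cannot be told from its own.

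**Figure D3:**
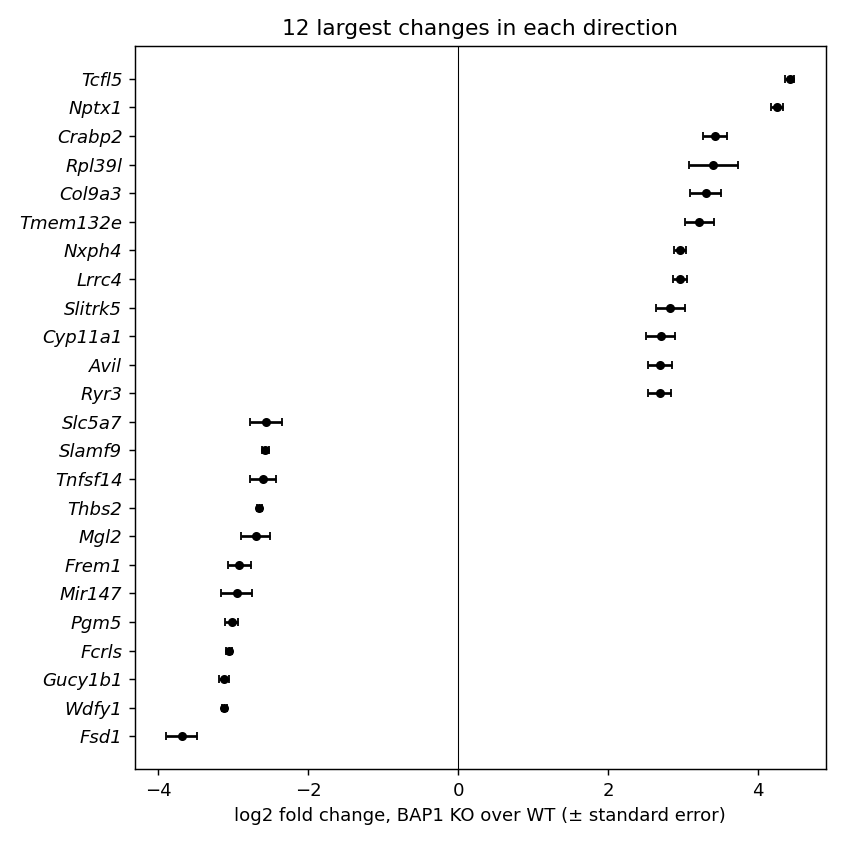
Log2 fold change of BAP1 KO over WT (horizontal axis) with its standard error for the 12 largest changes in each direction chosen by the rule. Rises reach 4.42 for Tcfl5 and falls -3.69 for Fsd1.

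Partners of BAP1 and subunits of the Polycomb complexes moved both ways, mostly by small amounts, and none of the 3 lists passed camera (adjusted p = 0.16, 0.68 and 0.58). Of 11 tested BAP1 partners, 7 rose, 3 fell and 1 did not pass; Asxl2, a cofactor of BAP1, rose by 0.34 ± 0.03, its paralogue Asxl3 by 1.62 ± 0.16 from 0.43 CPM, Hcfc1 by 0.18 ± 0.02 and Mbd5 by 0.32 ± 0.04. Among 21 subunits of Polycomb repressive complex 1 (PRC1), which ubiquitinates histone H2A, 4 rose, 8 fell and 9 did not pass, with Bcor at 0.36 ± 0.03, Phc1 at -0.40 ± 0.04 and Cbx6 at -0.34 ± 0.02. Rnf2, a catalytic subunit of PRC1, was at 47.4 CPM in WT and 44.8 CPM in BAP1 KO (adjusted p = 0.078, and 0.0074 to 0.92 over the alternatives). It passed with upper quartile factors, library totals alone, no filter on low counts or 1 surrogate variable, and without WT replicate 4 (-0.11). Of 11 PRC2 subunits, 4 fell, 0 rose (edgeR; 0 also at an unadjusted p of 0.05 and by DESeq2) and 7 did not pass; Jarid2 and Phf19 fell, with log2 fold changes of -0.53 ± 0.04 and -0.55 ± 0.05, and the methyltransferase Ezh2 with -0.13 ± 0.04. The call for Ezh2 was lost after removal of GC and length trends (-0.04, adjusted p = 0.25). The fall of Phf1, -0.10 ± 0.04 (adjusted p = 0.043), was lost with RLE factors, with DESeq2 and without a filter on low counts. It was also lost without each single library except WT replicate 1, and its adjusted p ran from 0.0022 to 0.12 over the alternatives; its exons overlap those of Cuta. Adjusted over the list alone, the counts were the same for the other lists of this group, and 3 PRC2 subunits fell.

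Genes that Polycomb complexes often control moved both ways. Among 24 tested Hox genes, 10 rose, 7 fell and 7 did not pass, or 10 and 10 adjusted over the list alone. Hoxb9 rose by 1.13 ± 0.05, while Hoxc4, Hoxc5 and Hoxc6, neighbours in a cluster, fell, with log2 fold changes of -0.99 ± 0.07, -1.18 ± 0.08 and -1.42 ± 0.13. Of 60 developmental transcription factors, 22 rose, 20 fell and 18 did not pass; Irx3 rose by 2.39 ± 0.15 from 0.40 CPM, and Tcf21, Foxc2 and Tbx4 fell by 0.76 ± 0.03, 0.88 ± 0.07 and 1.07 ± 0.09. Of 21 imprinted genes, 6 rose, 8 fell and 7 did not pass: Nnat rose by 2.23 ± 0.06 and Peg10 by 1.01 ± 0.03, and Peg3 and Slc38a4 fell by 1.48 ± 0.04 and 1.23 ± 0.03. In the last 2 lists the counts were the same adjusted over the list alone. None of these lists passed camera.

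Members of the BCL2 family changed in both directions. Bcl2 (Entrez 12043; chromosome 1, 106538176 to 106714290), an inhibitor of mitochondrial apoptosis whose exons overlap a transcript of the opposite strand over 497 bp, fell from 27.4 ± 0.84 to 16.2 ± 0.75 CPM (SD), a log2 fold change of -0.75 ± 0.04 (adjusted p = 1.5e-16). Mcl1 and Bcl2l1, other inhibitors at far higher levels, rose by 0.10 ± 0.02 and 0.14 ± 0.02, to 345.8 and 222 CPM. Bcl2a1b fell by 0.65 ± 0.07 and is uncertain, being a copy in a gene cluster. In all, 3 of 5 tested anti-apoptotic members rose and 2 fell. Of 10 pro-apoptotic members, 5 rose, 3 fell and 2 did not pass: Bbc3 (Puma) rose by 0.35 ± 0.06 and Bax by 0.23 ± 0.03, and Bmf and Bik fell by 0.68 ± 0.07 and 1.77 ± 0.23. Of 22 genes of caspases, the apoptosome and death receptors, 4 rose, 9 did not pass and 9 fell, among them Casp2 (-0.54 ± 0.04), Casp6 (-0.43 ± 0.04) and the death receptor Fas (-0.38 ± 0.04). Among 10 genes of IP3 receptors and mitochondrial calcium uptake, 4 rose, 1 fell and 5 did not pass, with rises of Itpr3 by 0.23 ± 0.03, Smdt1 by 0.19 ± 0.03, Vdac1 by 0.12 ± 0.02 and Itpr1 by 0.11 ± 0.03. Adjusted over the list alone, these counts were the same, and none of these lists passed camera.

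Most genes of the cell division cycle fell, by modest amounts, and a few rose. Of 52 G2M genes, 40 fell, 5 rose and 7 did not pass (41 and 5 adjusted over the list alone), with a median log2 fold change of -0.25 (camera adjusted p = 0.0044, and adjusted p = 0.27 with an estimated correlation). Top2a fell by 0.41 ± 0.03, Tmpo by 0.39 ± 0.03, Cdk1 by 0.34 ± 0.03 and Bub1 by 0.44 ± 0.04; Mki67 fell from 97.7 to 81.1 CPM. Of 44 S phase genes, 33 fell, 2 rose and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.078). The S phase list passed camera with limma-voom and without a filter on low counts, with adjusted p from 0.0011 to 0.28 over the alternatives. Prim1 fell by 0.62 ± 0.06 and Pola1 by 0.45 ± 0.04, and Rrm1 rose by 0.19 ± 0.02. Of 25 genes of homologous recombination and the DNA damage response, 13 fell, 2 rose and 10 did not pass, among them Blm (-0.45 ± 0.06), Rad51c (-0.86 ± 0.12), Brca1 (-0.30 ± 0.04) and Bard1 (-0.47 ± 0.07). The list of p53 targets, 32 genes, split into 12 rises, 9 falls and 11 that did not pass. The falls include Cdkn2a, which acts upstream of p53 and is not a target in the usual sense. Gdf15 rose by 0.78 ± 0.04 and Cdkn1a by 0.29 ± 0.02, and Plk2 fell by 0.40 ± 0.02. Both counts were the same adjusted over the list alone. Neither the homologous recombination list nor the p53 list passed camera (adjusted p = 0.58 and 0.59).

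Among 17 tumour suppressors associated with mesothelioma, 4 rose, 4 fell and 9 did not pass, also adjusted over the list alone. Cdkn2b, Cdkn2a and Mtap, neighbours on chromosome 4, fell, with log2 fold changes of -0.94 ± 0.03, -0.68 ± 0.04 and -0.51 ± 0.03; Cdkn2b went from 53.2 to 27.8 CPM. Stk3 fell by 0.27 ± 0.04. Nf2 was at 85.7 CPM in WT and 85.3 CPM in BAP1 KO (adjusted p = 0.84). The list did not pass camera.

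Most genes of the matrix and of fibroblasts fell. Of 30 tested, 22 fell, 5 rose and 3 did not pass, the same adjusted over the list alone, with a median of -0.26 (camera adjusted p = 6.5e-10, and adjusted p = 0.18 with an estimated correlation). Postn, a matrix protein of remodelling tissue, fell from 275.8 to 86.5 CPM (-1.67 ± 0.02), and Col14a1 and Cd34 fell by 1.19 ± 0.03 and 1.24 ± 0.04. Fbn1, the fibrillin of microfibrils, rose by 0.65 ± 0.02, and Col1a1 fell by 0.20 ± 0.02 from 8351 CPM. Of 27 mesothelial markers, 13 rose, 10 fell and 4 did not pass, also adjusted over the list alone. Wt1 rose by 0.45 ± 0.02 and the junction protein Cldn15 by 0.81 ± 0.03; Msln fell from 6.95 to 3.06 CPM (-1.19 ± 0.07), and Krt18, Efemp1 and Aldh1a2 fell by 1.39 ± 0.07, 0.84 ± 0.03 and 0.72 ± 0.02. Upk3b stood at 462 and 464 CPM and Krt19 at 3.19 and 3.31 CPM (adjusted p = 0.84 and 0.69).

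Epithelial junction genes counted 4 rises, 10 falls and 4 that did not pass among 18 tested, with Tjp1 at -0.30 ± 0.03, F11r at -0.23 ± 0.03 and Esrp2, a splicing factor, at 0.51 ± 0.05. Of 10 transcription factors and cadherins of epithelial-mesenchymal transition, 8 fell, 1 rose and 1 did not pass; Snai2 fell by 0.42 ± 0.05, Tcf4 by 0.34 ± 0.03 and Zeb1 by 0.18 ± 0.03. Among 20 TGF-beta response genes, 6 rose, 10 fell and 4 did not pass: Tgfbi fell by 0.92 ± 0.03, Ccn2 by 0.61 ± 0.02 and Tgfb3 by 0.50 ± 0.02. The 24 YAP targets gave 11 rises, 7 falls and 6 that did not pass, or 11 and 8 adjusted over the list alone, with Ccn2 at -0.61 ± 0.02, Ankrd1 at 0.91 ± 0.04, Crim1 at 0.32 ± 0.02 and Myof at 0.31 ± 0.02. Of 16 WNT targets and antagonists, 3 rose, 8 fell and 5 did not pass; the secreted antagonists Sfrp1 and Dkk3 fell by 1.51 ± 0.03 and 0.78 ± 0.02, and Sfrp2 and Ccnd1 rose by 0.40 ± 0.03 and 0.25 ± 0.02. For the lists without a second pair of counts here, the counts adjusted over the list alone were the same. None of these lists passed camera, though the WNT list did without WT replicate 1 (median -0.22), without a filter on low counts and with the stricter filter, and the TGF-beta list without a filter on low counts.

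Several macrophage and smooth muscle markers, such as Lyz2 and Acta2, were abundant in both genotypes, and markers of other cell types spanned a wide range of levels. Macrophage and myeloid markers split into 9 rises, 6 falls and 2 that did not pass among 17, with a median of 0.05: Lyz2 rose from 8388 to 11027 CPM (0.40 ± 0.02) and Lst1 by 0.91 ± 0.05, while Cd14 fell by 0.99 ± 0.02 and Itgam by 0.30 ± 0.02, and Ptprc, the leukocyte antigen CD45, from 153 to 118 CPM. Of 15 smooth muscle and pericyte markers, 6 rose, 5 fell and 4 did not pass; Cnn1, Myh11 and Actg2 rose by 0.35 ± 0.02, 0.33 ± 0.02 and 0.27 ± 0.02, Smtn fell by 0.33 ± 0.03, and Acta2 was at 5652 and 5659 CPM (adjusted p = 0.94); Acta2 passed, at 0.04, after removal of GC and length trends. Of 11 adipocyte markers, 7 rose, 3 fell and 1 did not pass, with a median of 0.49 (camera adjusted p = 0.045, and adjusted p = 0.27 with an estimated correlation). The adipocyte call was also lost without WT replicate 3 (median 0.45) or BAP1 KO replicate 4 (median 0.48) and under several settings, with adjusted p from 0.0072 to 0.28. Lpl, a lipase that macrophages also make, rose by 0.63 ± 0.02, Plin1 by 1.17 ± 0.07 and Car3 by 0.49 ± 0.04, Adipoq from 3.72 to 5.21 CPM, and Fabp4 fell by 0.39 ± 0.03. Of 10 endothelial markers, 3 rose, 6 fell and 1 did not pass, where Flt1 rose by 0.55 ± 0.04, and Kdr, Vwf and Lyve1 fell by 0.60 ± 0.05, 0.70 ± 0.06 and 0.54 ± 0.05; Pecam1 was at 0.44 and 0.38 CPM (adjusted p = 0.59). Of 12 neuronal genes, 6 rose, 2 fell and 4 did not pass, with Stmn2 at 1.20 ± 0.13, Uchl1 at 0.49 ± 0.04, Syn1 at -0.79 ± 0.06 and Ncam1 at -0.29 ± 0.03.

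Among 6 tested lymphocyte markers, Cd4 fell by 1.52 ± 0.11 to 1.14 CPM, and Cd79a (0.63 ± 0.17) and Cd2 (0.94 ± 0.35, at 0.19 CPM or less) rose; 3 did not pass. The call for Cd2 was lost without a filter on low counts, with DESeq2, without WT replicate 3 (0.87) and without BAP1 KO replicate 3 (0.83), and its adjusted p ran from 0.013 to 0.074 over the alternatives. The erythroid and the X-inactivation and Y-linked lists each had 1 tested member: Alas2, whose exons overlap Apex2, rose by 1.47 ± 0.10, and Xist was at 71.9 and 69.0 CPM. For all of these cell type lists, counts adjusted over the list alone were the same, and the lists other than adipocyte did not pass camera or had too few members.

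Most interferon-stimulated genes fell. Of 36 tested, 28 fell, 3 rose and 5 did not pass, the same adjusted over the list alone, with a median of -0.39 (camera adjusted p = 4.3e-05, and adjusted p = 0.073 with an estimated correlation). Ifit1 fell from 17.3 to 8.86 CPM (-0.97 ± 0.05), the RNA sensors Ifih1 and Ddx58 by 0.73 ± 0.04 and 0.51 ± 0.03, and the immunoproteasome subunit Psmb8 by 0.64 ± 0.03. Of 12 genes of MHC class I and antigen processing, 7 fell, 4 rose and 1 did not pass; Tap2 fell by 0.49 ± 0.03, and H2-D1 and H2-K1, uncertain because of related copies, rose by 0.31 ± 0.03 and 0.27 ± 0.02. Of 25 NF-kB and inflammatory genes, 14 rose, 11 fell and 0 did not pass: Vcam1, an adhesion molecule, fell from 184.7 to 79.0 CPM (-1.22 ± 0.03), Ptgs2 and Il33 by 0.74 ± 0.03 and 0.73 ± 0.04, and Relb rose by 0.60 ± 0.03. Of 24 immediate early and stress genes, 7 rose, 8 fell and 9 did not pass, or 8 and 8 adjusted over the list alone, with Egr2 at -1.03 ± 0.05, Atf3 at -0.40 ± 0.03, Hsph1 at -0.37 ± 0.03 and Klf6 at -0.22 ± 0.02. The MHC and NF-kB counts were the same adjusted over the list alone. The MHC, NF-kB and immediate early lists did not pass camera.

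Of 37 oxidative phosphorylation genes, 24 rose, 0 fell (edgeR; 0 also at an unadjusted p of 0.05 and by DESeq2) and 13 did not pass, the same adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.045, and adjusted p = 0.71 with an estimated correlation). The call was also lost without WT replicate 2, BAP1 KO replicate 1 or BAP1 KO replicate 2 (medians of 0.09, 0.09 and 0.10) and under several settings, with adjusted p from 0.00042 to 0.71. Ndufs3 rose by 0.37 ± 0.04, Cyc1 by 0.26 ± 0.03, Atp5b by 0.18 ± 0.02 and Sdha by 0.14 ± 0.02. Of 8 mitochondrially encoded genes, 0 rose, 0 fell and 8 did not pass (edgeR; 0 also at an unadjusted p of 0.05 and by DESeq2). Of 25 cholesterol synthesis genes, 16 fell, 4 rose and 5 did not pass (camera adjusted p = 0.063). This list passed camera with limma-voom and without a filter on low counts, with adjusted p from 0.0072 to 0.28 over the alternatives. Pmvk fell by 0.78 ± 0.05, Dhcr7 by 0.48 ± 0.04, Sqle by 0.47 ± 0.03 and Sc5d by 0.44 ± 0.03. Of 33 hypoxia and glycolysis genes, 15 rose, 10 fell and 8 did not pass, with Adm and Ndrg1 at 0.53 ± 0.02 and 0.53 ± 0.03, Pfkl at 0.41 ± 0.02 and Gpi1 at 0.39 ± 0.02. Of 24 genes of the unfolded protein response, 5 rose, 13 fell and 6 did not pass; Trib3 and Ddit3 rose by 1.07 ± 0.04 and 0.60 ± 0.04, and Pdia6 fell by 0.28 ± 0.02. Of 19 ferroptosis and glutathione genes, 8 rose, 7 fell and 4 did not pass: Slc7a11, the cystine transporter, rose by 0.87 ± 0.05, Tfrc by 0.45 ± 0.03, Srxn1 by 0.24 ± 0.02 and Hmox1 by 0.17 ± 0.02. These other counts were the same adjusted over the list alone. The mitochondrially encoded, hypoxia, unfolded protein response and ferroptosis lists did not pass camera.

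**Figure D4:**
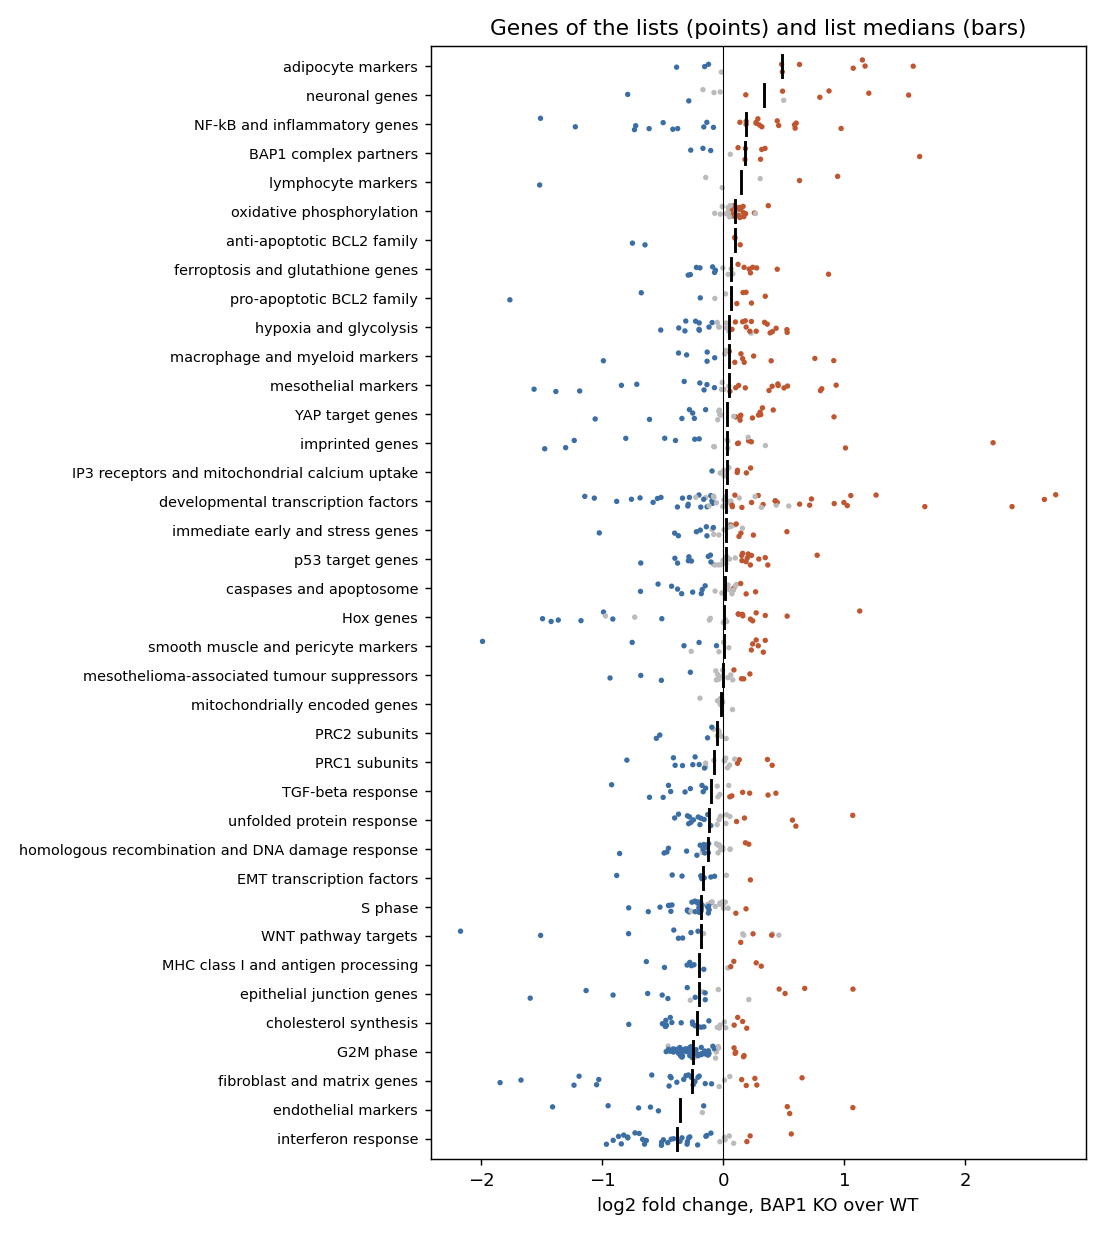
Log2 fold change of BAP1 KO over WT (horizontal axis) for the genes of the 38 tested lists (rows, ordered by median), with points in orange for rises, blue for falls and grey for genes that did not pass, and list medians as black bars. Medians of the interferon and matrix lists are -0.39 and -0.26, and that of the adipocyte list is 0.49.

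In all, 5 of the 38 lists passed camera with the preset correlation, 2 up and 3 down. With an estimated correlation 0 passed, 6 had an unadjusted p under 0.05, and the smallest adjusted p was 0.073. By fry, which asks whether the genes of a list move on balance one way, 34 lists passed. Because fry does not compare a list with other genes and 61.1% of all tested genes were called, this count does not set the lists apart. Median, mean and camera direction differed in sign for the Hox, anti-apoptotic, pro-apoptotic, caspase, mesothelial, smooth muscle, lymphocyte, NF-kB, immediate early, imprinted and mitochondrially encoded lists.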

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

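The tests of GC and length trends, of chromosome copies, of repeat libraries, of Bap1 and of macrophage share were chosen after the results were seen. Among 352 groups of 4 values for named genes and library totals, 13 held a library far from the other 3, where chance gives about 17.6, so no pattern is read from them. In WT these were Gucy1b1 at 15.4 CPM against 14.5 to 14.6 and Slc38a4 at 70.0 against 73.2 to 73.8 in replicate 1, Pgm5 at 10.3 against 9.66 to 9.72 and Tgfb3 at 136 against 131 in replicate 2, Rrm1 at 338 against 330 to 331 in replicate 3, and Psmb8 at 49.8 against 46.4 to 46.8 in replicate 4. In BAP1 KO they were Avil at 2.37 CPM against 2.21 to 2.23, Rnf2 at 41.7 against 45.5 to 46.2 and Egr2 at 10.6 against 9.24 to 9.35 in replicate 1, Cdkn2b at 29.0 against 27.3 to 27.4 and Srxn1 at 155 against 151 in replicate 2, and Lyz2 at 10700 against 11100 to 11200 and Tap2 at 33.2 against 34.7 to 34.9 in replicate 3.

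The number of genes called, 61.1% of those tested, is a first pattern. The real split was the only 1 of the 35 splits of the 8 libraries into 4 and 4 with as many genes higher (4908, against at most 0 by edgeR in the others, where up to 1417 genes had an unadjusted p under 0.05), and likewise 1 of 35 for lower genes (5432 against 0); in the mixed splits the genotype difference adds to the spread within each group. After removal of GC and length trends the number of calls, new ones included, was 107% of the first. Of the 10340 first calls, 9655 were kept in the same direction. No chromosome median moved by more than 0.064. Neither a GC or length trend nor gain or loss of a whole chromosome therefore accounts for most of the calls. Whether the libraries of a genotype are repeat libraries of 1 culture cannot be told apart from a genotype effect: their coefficient of variation was 0.029, and the labels name no cultures. In that case the calls could reflect differences between 2 cultures as well as BAP1, and a genotype effect stays a hypothesis.

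For the number of lists past the threshold, chance is not excluded by the count of splits. As many lists as the real 5 passed in 16 of the 35 splits, the real one included, with a highest of 8 in the others. However, the 15 others with as many all hold 3 libraries of a genotype in a group, and so carry part of the genotype difference. The 18 splits with 2 libraries of each genotype in each group balance the genotypes, yet they gave 0 to 4 lists. Camera at the preset correlation can therefore pass lists where the groups do not differ in genotype. The real 5 may include such calls.

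Bap1 fell only to 84.2% of the WT level. A swap of single libraries between the genotypes is argued against, since 0 of the 4 BAP1 KO libraries reached the WT range. A wrong label of a whole group is not tested by this, because the genotypes also did not overlap in 53.8% of all tested genes. Whether the remaining reads come from cells that kept an intact allele, or from exons that remain in a deleted allele, cannot be told apart, because counts per gene hold no exon and the 84.2% may arise either way.

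The falls of Fcrls, Slamf9 and Mgl2, singled out after their values were seen, have a median of -2.70. A lower share of macrophages would lower all of their transcripts alike. The macrophage and myeloid list had a median of 0.049, above those falls by 2.75, which is more than the spread of its members (SD 0.43). Those genes were chosen from the 12 largest falls, so that gap was set by the choice and weighs neither way. What bears on the share is the list itself. Of its 17 members, 9 rose, among them Lyz2 to 11027 CPM, and 6 fell, among them Cd14 (-0.99), Ptprc (-0.37) and Itgam (-0.30). A smaller share of all macrophages alike is therefore argued against as the whole cause. A change in the state of macrophages, or an effect of genotype on them, stays open and was not tested.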

How the results depend on the processing

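No paired analysis was possible because the labels give no replicate numbers shared between the genotypes. The removal of GC and length trends was chosen after seeing the data. Bap1 stayed lower in every alternative that recorded a value for it, at -0.26 to -0.24 with single libraries left out. The test against a 1.5-fold change recorded none for Bap1. Leaving out single libraries gave 4650 to 4883 higher and 5172 to 5370 lower genes and 4 to 6 lists. Against a 1.5-fold change, 370 genes were higher and 1014 lower, because most calls are smaller than that. Upper quartile factors and library totals alone each gave 3 lists, losing the adipocyte and oxidative phosphorylation lists; no filter on low counts gave 9 lists, adding S phase, TGF-beta, WNT and cholesterol synthesis (S phase and cholesterol synthesis also passed with limma-voom), and the estimated correlation 0. For the first 3 of these the cause was not tested. The estimated correlation was above the preset 0.01 for the G2M (0.035), matrix (0.108), adipocyte (0.017) and oxidative phosphorylation (0.292) lists. For the interferon list it was 0.003, so a higher correlation does not account for the loss of that call. With an estimated correlation, camera also tests on the residual degrees of freedom, 6 here, and with a preset one on far more. That difference applies to every list, and how much it and the correlation each contributed was not tested. With RLE factors, GC correction and DESeq2 the higher genes were 5159, 5821 and 4987 and the lower genes 5251, 5216 and 5073. Of 2953 values for 174 named genes, 2932 kept their call, 15 were no longer past the threshold, 6 passed newly and 0 reversed; Phf1, Rnf2, Cd2, Ezh2 and Acta2 were the genes that moved. Of 645 values for 38 lists, 620 kept their call, 17 lost it, 8 gained it and 0 reversed. The depth of 67.1 M counts or more does not limit abundant genes, but genes near 0.1 CPM rest on few counts.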

Other observations

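The tests of Hox genes, of the Cdkn2a region and of matrix genes were chosen after the results were seen, and the abundant genes were chosen after their values were seen. Among genes above 1000 CPM in a genotype, Spp1 (osteopontin), a secreted phosphoprotein made by macrophages and matrix-forming cells, fell most, from 2714 ± 64 to 607 ± 6.1 CPM (SD, n = 4), a log2 fold change of -2.16 ± 0.02 (edgeR adjusted p = 1.4e-35). Fn1 fell from 13164 to 9757 CPM and Col3a1 from 4197 to 3094 CPM. Col4a1, Col4a2 and Hspg2 (perlecan) rose by 0.43 ± 0.02, 0.45 ± 0.02 and 0.54 ± 0.03. Marco, a scavenger receptor of macrophages, rose from 553 to 1008 CPM, and the complement component C3 from 1239 to 1891 CPM.

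A hypothesis was that BAP1 loss, acting on ubiquitinated histone H2A, changes developmental regulators more than other genes. The median size of change of the 60 developmental transcription factors was 0.29, at percentile 81.6 among 10000 random lists matched on expression, where the random median was 0.25. For the 24 Hox genes the median was 0.31, at percentile 87.8, against 0.23. Neither passed the 95th percentile set for the test, so these data do not bear the hypothesis out for either list as a whole. A median does not show a change of only some members. At 2-fold or more, 7 of the 60 developmental factors rose and 2 fell, and 1 of the 24 Hox genes rose and 4 fell. Among all 16929 tested genes, 312 rose and 772 fell by as much. These counts were not compared with genes of like abundance, so a subset was not tested.

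Another hypothesis was that part of the BAP1 KO cells lost the segment of chromosome 4 with Cdkn2a, Cdkn2b and Mtap, a frequent loss in mesothelioma. If every cell expressed these genes in the same proportions, loss of the segment would lower them by the same share, and Mtap fell less than Cdkn2b by 0.42 ± 0.045 on the log2 scale. Which cells supply each transcript was not measured, so loss of the segment cannot be told apart from other regulation, and DNA was not analysed here.

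Fewer fibroblast-like cells could explain the falls of matrix genes. Of the fibroblast and matrix list, 5 members passed the test in the other direction, among them Fbn1 and Fbln2, while Fap, Dpt and Lum, also named after their values were seen, fell by 1.85, 1.05 and 1.03. Mesothelial cells make many matrix genes too, so fewer fibroblast-like cells cannot be told apart from a change within the cells.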
